A study of Mus musculus with 24 samples.

How the data were processed

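Total RNA was sequenced from Myc-CaP cells, a mouse prostate tumour line driven by the MYC oncogene, after 6 days of continuous treatment, with medium and drug renewed every 3 days. There were 8 groups of 3 libraries, 24 in all. Controls received the solvent DMSO. The drugs were 500 nM PF-06873600, an inhibitor of CDK2, CDK4 and CDK6, 1 µM palbociclib, an inhibitor of CDK4 and CDK6, 500 nM alisertib, an inhibitor of Aurora kinase A, 3.75 µM docetaxel, which stabilises microtubules, 500 nM etoposide, which traps topoisomerase II on DNA, and 500 nM Nutlin, which blocks the binding of MDM2 to p53. A further group is labelled T/P. The treatment protocol lists 25 nM trametinib, an inhibitor of the kinases MEK1 and MEK2, for no other group, and T/P was read as trametinib with 1 µM palbociclib. All libraries carry the label batch 1.

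The authors trimmed reads with fastp, aligned them with STAR to the mouse build mm10 and counted them per gene with featureCounts, and their notes name DESeq2. The labels give no versions, and the sources used do not state the strand setting or how reads with several alignments were treated. Genes with near-identical copies, such as Apol9b, Ifit3, the tubulins and the MHC class I genes, can therefore share reads. The deposited count table holds raw counts for 55487 genes. The deposited TPM table holds TPM (counts scaled to transcript length and library size) for 24621 genes, those with at least 10 counts in all libraries together. Gene positions come from GENCODE vM21 on the same build and span the whole gene, and counts are over annotated exons.

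The lowest total count was 21260781. Counting error at this depth is small for genes at 10 CPM (counts scaled to library size) and large for genes near 0, so genes with at most 4 counts over the 3 DMSO libraries are given by level and not by fold. A check for repeated libraries gave a chi-square per degree of freedom between 2.78 and 49.3 for the 24 pairs of libraries within a group, so none was a copy of another in its group. Pairs across groups were not compared.

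Differential expression was tested on the counts in R 4.3.3 with edgeR 4.0.16. One quasi-likelihood fit held all 24 libraries with a mean per group, TMM scaling factors and 16 residual degrees of freedom. The filter filterByExpr, with a minimum count of 10 and a minimum total of 15, left 15527 genes, which hold 99.9% of all counts. Each of 7 treatments was compared with DMSO, and 4 comparisons were made between treatments. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Log2 fold changes are given with their standard error, and levels as mean CPM with the SD of the 3 libraries. The p-values measure the spread between these libraries alone, since the labels do not say whether the 3 libraries of a group came from separate cultures.

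The comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. Of 31 gene lists, 28 had the minimum of 4 tested members. They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Beside each list stand the members called in the gene test and the count adjusted over the list alone. An estimated correlation and the rotation test fry, which asks whether a list's genes move one way and does not compare them with other genes, were alternatives. Named genes were the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM, an established symbol and all 3 treated libraries on 1 side of all 3 controls, up to 3 members of each of up to 7 called lists, the drug targets and a fixed set led by Cdkn1a and Mki67. Comparisons between treatments took 3 rises, 3 falls and up to 2 members of each of up to 4 lists.

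The pipeline was tested on counts simulated from the gene means in DMSO, their spread and the real library sizes. In the libraries standing for Nutlin, 50 genes were changed at each size. It tested 13734 genes. It found 80% of genes raised 1.5-fold, 92% for 2-fold, 98% for 4-fold and 72% of those lowered to 0.667. Of 178 calls, 3.93% were false. So few changes do not test scaling or error with many genes changed.

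Alternatives were RLE factors, total counts as the only scaling, DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 3 libraries, a minimum change of 2-fold, fits of only the 2 groups compared, a block for the number of the library and leaving out each library in turn. Leaving out the libraries numbered 2, and limma on log2(TPM + 1) of the deposited TPM, were chosen after seeing the data. Scaling by total counts shifted the median of all genes by 0.20 for alisertib, 0.21 for docetaxel and 0.21 for etoposide on the log2 scale, and changes are relative to the TMM scaling. The labels do not pair libraries across groups. In 5 of 11 comparisons, those of PF-06873600, alisertib and etoposide with DMSO, docetaxel with alisertib and etoposide with docetaxel, the deviations of libraries with the same number correlated above 0.1 in every pair, and 19 of 24 libraries were closest to a library of their own number. With the number as a block, these 5 gave 5992, 9332, 9343, 3950 and 5947 called genes. No library was left out of the analysis.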

Results

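Gene expression was measured by bulk RNA sequencing in Myc-CaP mouse prostate tumour cells after 6 days with the solvent DMSO or 1 of 7 drug treatments, with 3 libraries in each of 8 groups. Total counts were between 21260781 and 28318784 in 23 libraries and 69757257 in Docetaxel 1. On the first principal component, which held 49.0% of the variance, the group means were -80.6 for Nutlin, -68.9 ± 0.619 (SD, n = 3) for DMSO, -24.4 for T/P, -22.2 for palbociclib, 7.05 for PF-06873600, 61.2 for docetaxel, 61.7 for alisertib and 66.2 for etoposide. The second component held 10.7% of the variance, and every library numbered 2 except Palbociclib 2 stood apart from its group on it. In these libraries transcripts kept in the nucleus were low. Neat1, a long noncoding RNA of nuclear paraspeckles, had 42.7 counts scaled to library size (CPM) in DMSO 2 against 154 and 172 in the other DMSO libraries, and 449 in Palbociclib 2 against 544 and 610. Levels are mean CPM ± SD, changes are log2 fold changes ± standard error from the edgeR quasi-likelihood fit, and n = 3 per group throughout. Pairs of counts for a gene list adjusted over the list alone give members higher first. A list called by camera with a preset correlation between genes had an adjusted p under 0.05 with an estimated correlation too, unless that p is given. Each gene given among the largest rises or falls against DMSO had all 3 treated libraries beyond all 3 DMSO libraries. The series is about drugs that bring on senescence and agents that remove senescent cells, and each comparison with DMSO asks which genes a drug changed after 6 days.

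**Figure D1:**
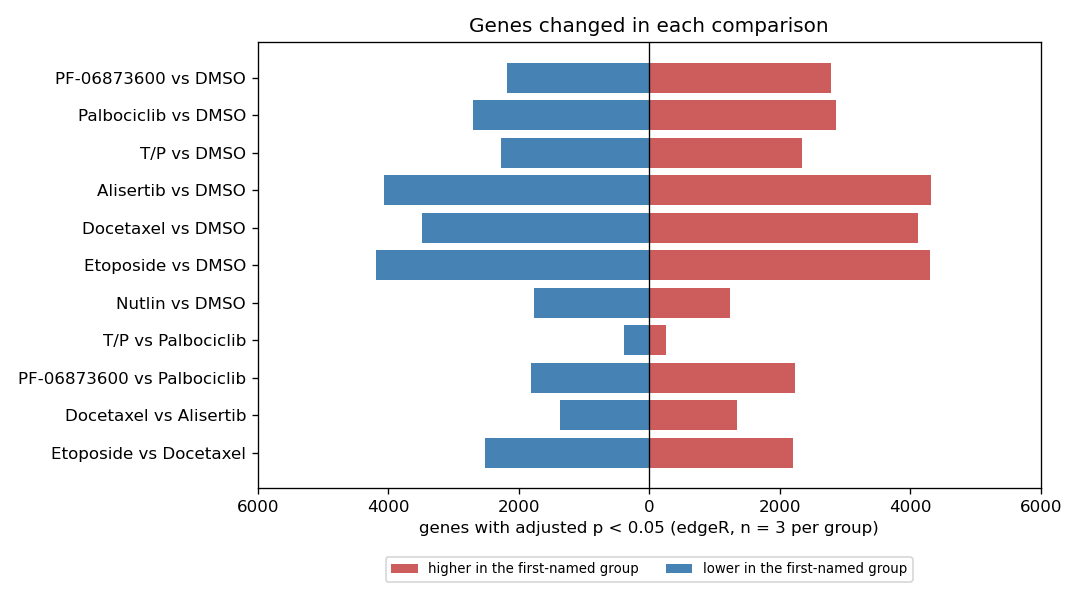
Number of genes called (edgeR, adjusted p under 0.05, n = 3 per group) in each of 11 comparisons, with genes higher in the first-named group to the right and lower ones to the left. Etoposide against DMSO gave 8485 genes and T/P against palbociclib 637.

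Alisertib, which inhibits Aurora kinase A and so disturbs the mitotic spindle, raised Ccl9 most among the named genes. This chemokine gene (ENSMUSG00000019122.8, chromosome 11, 83572919 to 83578636, build mm10) rose from 0.225 ± 0.108 to 28.2 ± 4.79 CPM, a log2 change of 6.96 ± 0.315 (edgeR adjusted p = 2.44e-14). Postn, which encodes the matrix protein periostin, rose to 53.5 ± 5.74 CPM, by 6.65 ± 0.172 on the log2 scale. The complement gene C3 rose 54.2-fold to 152 ± 18.6 CPM, Glrb, a glycine receptor subunit, 53.8-fold, and Il1rl1, the receptor of interleukin-33, 50.1-fold. Krt78, a keratin gene, fell 28.4-fold from 94.5 ± 14 to 3.33 CPM (log2 change -4.83 ± 0.211), Krt4 11.2-fold from 629 to 56.1 CPM and the serine protease gene Prss8 12.8-fold from 50.1 to 3.91 CPM. Arg1, which encodes arginase, changed by -3.96 and the early-response nuclear receptor gene Nr4a1 by -3.92 on the log2 scale.

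Cell cycle genes were higher with alisertib than in DMSO. Of 54 G2 and mitosis genes, 47 were higher and 3 lower (48 and 3 adjusted over the list alone, camera adjusted p = 7.2e-17, adjusted p = 0.19 with an estimated correlation). Aurka, the gene of the drug's target (ENSMUSG00000027496.15, chromosome 2, 172356190 to 172370535), rose 3.84-fold from 24.6 ± 0.975 to 94.7 ± 3.51 CPM (edgeR adjusted p = 3.11e-10). The spindle genes Dlgap5 and Kif20b rose by 1.77 and 1.67, and Mki67, which encodes a marker of cycling cells (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361), rose 2.71-fold from 69.8 ± 7.58 to 189 ± 8.82 CPM. Among 43 S phase genes 38 were higher and 2 lower (38 and 2 adjusted over the list alone, camera adjusted p = 3.45e-10, adjusted p = 0.201 with an estimated correlation), with rises of 3.33-fold for the helicase gene Cdc45, 1.38 for Dtl and 0.95 for E2f1 on the log2 scale. All 18 genes of homologous recombination and the Fanconi pathway were higher (18 adjusted over the list alone, camera adjusted p = 1.23e-10, adjusted p = 0.0778 with an estimated correlation), among them Bard1 at 3.63-fold and Brca2 at 2.46-fold. Cdkn1a, which encodes the CDK inhibitor p21 (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727), rose 2.57-fold from 27.9 ± 0.985 to 71.6 ± 6.57 CPM (log2 change 1.36 ± 0.076, edgeR adjusted p = 8.34e-13).

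With alisertib interferon-stimulated genes were higher for 33 of 37 members with 0 lower (35 and 0 adjusted over the list alone, camera adjusted p = 1.25e-07, adjusted p = 0.236 with an estimated correlation), among them Usp18 at 21.9-fold and Gbp2 at 9.93-fold. NF-kB targets were higher for 13 of 17 and lower for 2 (13 and 2 adjusted over the list alone, camera adjusted p = 1.9e-05). Tnfaip2 rose 14.3-fold and Relb, a subunit of NF-kB, 5.02-fold. Of 14 tested cytokine genes of the senescence-associated secretory phenotype, from 27 listed, 11 were higher (12 adjusted over the list alone, camera adjusted p = 2.88e-05), including Csf1, a macrophage growth factor, at 2.43-fold and Cx3cl1 at 3.48-fold. Ccl2, with 4 counts over the DMSO libraries, reached 1.16 ± 0.369 CPM (edgeR adjusted p = 1.9e-05), and Cxcl10, with 3 counts there, reached 0.813 ± 0.0657 CPM (adjusted p = 5.82e-06). Protease, matrix and growth factor genes of that phenotype were higher for 17 of 25 and lower for 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.000458). Vim, which encodes the mesenchymal filament protein vimentin, rose 6.75-fold and the collagen gene Col4a2 by 1.89, and 12 of 14 mesenchymal and matrix genes were higher (12 adjusted over the list alone, camera adjusted p = 8.52e-07). The 4 tested of 9 listed fibroblast markers were higher (4 adjusted over the list alone, camera adjusted p = 0.021, 0.0778 with an estimated correlation). So were the 3 tested of 7 endothelial and 3 tested of 8 MHC class II genes, too few for a list test.

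Luminal epithelial markers were lower for 6 of 8 and higher for 1 with alisertib (the same adjusted over the list alone, camera adjusted p = 0.000348, adjusted p = 0.0891 with an estimated correlation). Of 14 output genes of the MAPK pathway, 10 were lower and 2 higher (2 and 10 adjusted over the list alone, camera adjusted p = 0.000289, adjusted p = 0.0788 with an estimated correlation). Tubulin and microtubule genes were higher for 14 of 16 (14 adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.173 with an estimated correlation). Of 47 genes of ribosome biogenesis that MYC drives, 20 were lower and 3 higher (3 and 20 adjusted over the list alone, camera adjusted p = 0.00221, adjusted p = 0.247 with an estimated correlation). Immune ligand genes were higher for 12 of 15 and lower for 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0114), and Cd274, the gene of PD-L1, rose 2.51-fold from 1.31 ± 0.387 CPM. Mdm2 rose 1.21-fold (adjusted p = 0.00159). Lmnb1, the lamin B1 gene, B2m and the anti-apoptotic gene Bcl2l1 had log2 changes of 0.03 (adjusted p = 0.836, and 0.0448 with limma on TPM), -0.08 (0.504) and -0.03 (0.707). Cdkn2a, the gene of p16 and ARF, had -0.31 (adjusted p = 0.0301), with 0.0504 under RLE factors, 0.0548 in DESeq2, 0.326 with total counts, 0.0506 with only the 2 groups, 0.608 with limma on TPM, 0.148 and 0.0564 without DMSO 1 and 2 and 0.176 without Alisertib 3. In all, 8371 genes were called, 4313 higher and 4058 lower, and 2848 changed at least 2-fold. The share of calls that were higher was 51.5%, and 71.8% with total counts as the scaling.

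Docetaxel, a taxane that stabilises microtubules, changed tubulin genes. Tubb5, a beta-tubulin gene, rose 2.58-fold from 691 ± 28.4 to 1790 ± 147 CPM (log2 change 1.37 ± 0.0758, edgeR adjusted p = 1.34e-12). Tubb2a rose 4.92-fold to 61.3 CPM and Tubb2b, a close copy of it, 8.05-fold to 38 CPM. Of 16 tubulin and microtubule genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 7.96e-08, adjusted p = 0.0865 with an estimated correlation). Cholesterol synthesis and uptake genes were higher for 20 of 24 with 0 lower (22 and 1 adjusted over the list alone, camera adjusted p = 3.06e-08), with rises of 2.84-fold for Hmgcs1, 2.8-fold for Idi1 and 2.07-fold for Msmo1, enzymes of the pathway. The largest rises were again in Postn at 73.7-fold, Ccl9 at 72.3-fold, C3 at 45.7-fold, Il1rl1 at 21.9-fold and Glrb at 14.7-fold. Among the largest falls, Ccn1, a matrix-associated signalling gene, fell 8.59-fold from 2200 ± 59.1 to 255 ± 25.6 CPM (log2 change -3.1 ± 0.0971, edgeR adjusted p = 9.87e-17). Cps1, an enzyme of the urea cycle, fell 9.94-fold from 429 ± 50.3 to 43.1 CPM, Krt78 17.8-fold and the early-response gene Fosb 14.4-fold, and Nr4a1 changed by -3.03 on the log2 scale.

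Of 54 G2 and mitosis genes, 40 were higher with docetaxel and 2 lower (42 and 3 adjusted over the list alone, camera adjusted p = 5.2e-09, adjusted p = 0.381 with an estimated correlation). Aurka rose 2.58-fold to 63.7 CPM, Nusap1 by 1.3 on the log2 scale and Mki67 1.92-fold to 134 ± 16.8 CPM (edgeR adjusted p = 0.000143). Of 43 S phase genes, 25 were higher and 3 lower (26 and 3 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.476 with an estimated correlation). Of 18 recombination repair genes, 16 were higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 3.54e-06, adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes were higher for 33 of 37 with 0 lower (34 and 0 adjusted over the list alone, camera adjusted p = 7.96e-08, adjusted p = 0.261 with an estimated correlation), Usp18 by 21.4-fold. NF-kB targets were higher for 14 of 17 and lower for 2 (the same adjusted over the list alone, camera adjusted p = 8.78e-07), with Relb up 5.49-fold and Tnfaip2 9.21-fold. Secretory cytokine genes were higher for 12 of 14 (12 adjusted over the list alone, camera adjusted p = 1.11e-05). Cx3cl1 rose 4.43-fold and the chemokine gene Cxcl1 2.75-fold, and Ccl2 and Cxcl10 reached 0.83 ± 0.38 and 0.617 ± 0.00416 CPM (adjusted p = 0.000126 and 3.33e-05).

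Mesenchymal genes were higher with docetaxel for 10 of 14 (the same adjusted over the list alone, camera adjusted p = 1.66e-05). Of 25 matrix and growth factor genes of the secretory phenotype, 19 were higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 9.38e-05). All 4 tested fibroblast markers were higher (the same adjusted over the list alone, camera adjusted p = 0.0172, 0.0747 with an estimated correlation). So were the 3 endothelial and 3 MHC class II genes tested. Genes of the unfolded protein and integrated stress responses were lower for 13 of 23 and higher for 5 (5 and 13 adjusted over the list alone, camera adjusted p = 0.000112, adjusted p = 0.185 with an estimated correlation). Xbp1, a transcription factor gene of the unfolded protein response, changed by -1.6 and the chaperone gene Dnajb9 by -1.47, while Ddit3 rose by 1.4. Luminal markers were lower for 6 of 8 and higher for 2 (the same adjusted over the list alone, camera adjusted p = 0.000551, adjusted p = 0.125 with an estimated correlation). Of 14 MAPK output genes, 8 were lower and 2 higher (3 and 8 adjusted over the list alone, camera adjusted p = 0.0309, adjusted p = 0.272 with an estimated correlation). Cdkn1a rose 1.89-fold to 52.8 ± 1.98 CPM (log2 change 0.92 ± 0.0756, edgeR adjusted p = 9.85e-10) and Cd274 2.52-fold. The log2 change of Mdm2 was 0.2 (adjusted p = 0.0174), and without Docetaxel 3 its adjusted p was 0.163, without Docetaxel 1 0.101, without DMSO 1, 2 or 3 0.0716, 0.103 or 0.069, with no filter 0.193 and with only the 2 groups 0.0571. Lmnb1 had -0.14 (adjusted p = 0.294), Bcl2l1 -0.11 (0.224), Cdkn2a -0.01 (0.941) and B2m -0.19 (0.125, with 0.0215 without DMSO 3, 0.0308 with no filter, 0.0276 under the block and 0.0458 without the libraries numbered 2). In all, 7608 genes were called, 4121 higher and 3487 lower, and 2616 changed at least 2-fold. Higher calls made up 54.2% of these, and 78.4% with total counts as the scaling.

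Etoposide, which leaves DNA breaks by trapping topoisomerase II, changed 8485 genes, 4305 higher and 4180 lower, of which 3010 changed at least 2-fold. Ccl9 rose 194-fold to 43.8 ± 4.44 CPM (log2 change 7.6 ± 0.31, edgeR adjusted p = 3.02e-15), Il1rl1 90.5-fold to 45.6 CPM, Postn 76.1-fold, C3 52.2-fold and Apol9b 43-fold from 1.11 to 47.9 ± 18.9 CPM, a gene with a near-identical neighbour. Calca, the precursor gene of calcitonin, fell 21.1-fold from 96 ± 4.01 CPM (log2 change -4.4 ± 0.118, adjusted p = 5.25e-18). The luminal keratin gene Krt19 fell 19.3-fold from 76 ± 5.74 CPM, Prss8 17.9-fold, Krt78 11.6-fold, and Nr4a1 changed by -3.54. Top2a, a gene of the drug's target (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189), rose 2.1-fold from 212 ± 29.6 to 446 ± 35.3 CPM (log2 change 1.07 ± 0.184, adjusted p = 3.16e-05).

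Replication and repair genes rose with etoposide. S phase genes were higher for 40 of 43 and lower for 2 (40 and 2 adjusted over the list alone, camera adjusted p = 1.77e-17, adjusted p = 0.125 with an estimated correlation), with Cdc45 up 4.38-fold and the cyclin E1 gene Ccne1 2.79-fold. G2 and mitosis genes were higher for 48 of 54 and lower for 1 (48 and 1 adjusted over the list alone, camera adjusted p = 4.28e-18, adjusted p = 0.157 with an estimated correlation), with Aurka up 3.78-fold to 93.1 CPM, Mki67 2.65-fold to 185 CPM and Mybl2, a transcription factor of late cell cycle genes, by 1.39. All 18 recombination repair genes were higher (the same adjusted over the list alone, camera adjusted p = 6.36e-12, adjusted p = 0.0599 with an estimated correlation), Bard1 by 5.26-fold to 34 CPM. Cdkn1a rose 2.64-fold to 73.6 ± 2.17 CPM (log2 change 1.4 ± 0.076, edgeR adjusted p = 3.57e-13). Lmnb1 rose 1.34-fold (adjusted p = 0.0025). Tubulin genes were higher for 14 of 16 and lower for 1 (the same adjusted over the list alone, camera adjusted p = 3.94e-06, adjusted p = 0.125 with an estimated correlation).

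Of 37 interferon-stimulated genes, 36 were higher with etoposide and 0 lower (36 and 0 adjusted over the list alone, camera adjusted p = 2.86e-12, adjusted p = 0.125 with an estimated correlation), Usp18 by 39.5-fold and Ifi27 5.09-fold to 146 ± 38.9 CPM. Of 17 NF-kB targets 15 were higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 2.25e-06), with Tnfaip2 up 19.2-fold and Relb 7.18-fold. Secretory cytokine genes were higher for 12 of 14 (the same adjusted over the list alone, camera adjusted p = 2.65e-06). Csf1 rose 4.62-fold from 27.1 ± 1.02 to 125 ± 5.5 CPM (log2 change 2.21 ± 0.0692, edgeR adjusted p = 3.67e-17) and Cx3cl1 4.85-fold, while Ccl2 and Cxcl10 reached 1.52 ± 0.325 and 1.39 ± 0.131 CPM (adjusted p = 4.01e-06 and 2.21e-07). Mesenchymal genes were higher for 12 of 14 (the same adjusted over the list alone, camera adjusted p = 3.21e-06), with Vim up 5.24-fold to 780 CPM and Col4a2 4.81-fold. Of 25 matrix and growth factor genes of the secretory phenotype 17 were higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.000365). Fibroblast markers were higher for 3 of 4 tested, which did not pass as a list (camera adjusted p = 0.0728). The 3 endothelial and 3 MHC class II genes tested were higher.

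Immune ligand genes were higher with etoposide for 11 of 15 and lower for 3 (the same adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.0599 with an estimated correlation), and Cd274 rose 2.6-fold (adjusted p = 5.22e-05). Luminal markers were lower for 6 of 8 and higher for 2 (the same adjusted over the list alone, camera adjusted p = 0.00253, adjusted p = 0.125 with an estimated correlation). Of 14 MAPK output genes, 9 were lower and 2 higher (the same adjusted over the list alone, camera adjusted p = 0.0313, adjusted p = 0.249 with an estimated correlation). Basal epithelial markers were higher for 6 of 9 and lower for 1 (the same adjusted over the list alone, camera adjusted p = 0.0313, adjusted p = 0.125 with an estimated correlation), and without the libraries numbered 2 the camera adjusted p was 0.0616. Androgen response genes were higher for 5 of 16 and lower for 8, with a median log2 change of -0.29 and a mean of 0.17 (5 and 9 adjusted over the list alone, camera adjusted p = 0.0423, adjusted p = 0.32 with an estimated correlation, and 0.0547 without Etoposide 1). Bcl2l1, Cdkn2a and Mdm2 had log2 changes of -0.09 (edgeR adjusted p = 0.273), -0.04 (0.804) and 0.16 (0.0545). For Mdm2 it was under 0.05 in 9 alternatives, from 0.00107 with total counts to 0.0447 with only the 2 groups, with 0.0192 under the block for library number and 0.0262 without Etoposide 2. The log2 change of B2m was -0.29 (adjusted p = 0.0153), with 0.351 with total counts, 0.344 with limma on TPM, 0.0855 with only the 2 groups, 0.0864 without DMSO 1 and 0.104 without Etoposide 3. Higher calls were 50.7% of all calls, and 71.6% with total counts as the scaling.

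**Figure D2:**
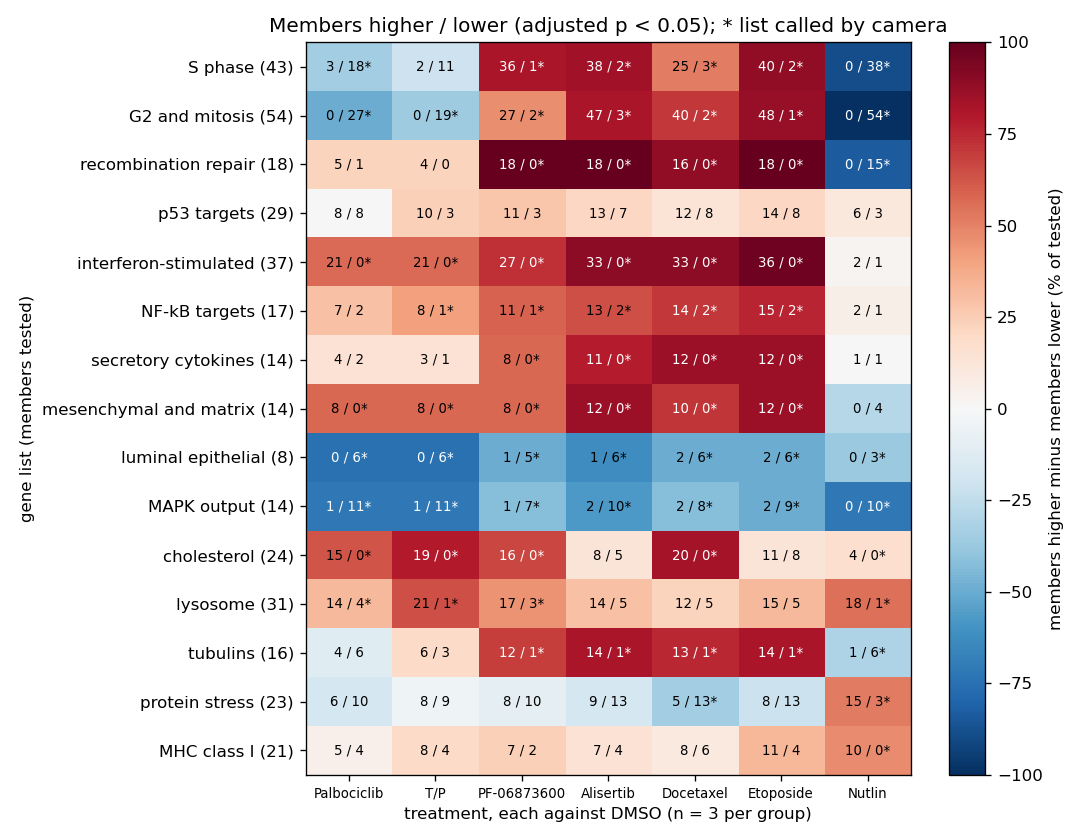
Members of 15 gene lists called higher / lower in each treatment against DMSO (edgeR, n = 3 per group), with the number of members tested in brackets and colour for members higher minus members lower in percent of those tested. An asterisk marks lists called by camera with the preset correlation, and the 54 G2 and mitosis genes go from 48 higher and 1 lower with etoposide to 0 higher and 54 lower with Nutlin.

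PF-06873600, the inhibitor of CDK2, CDK4 and CDK6, raised Il1rl1 (ENSMUSG00000026069.15, chromosome 1, 40429570 to 40465415) 62.4-fold from 0.502 ± 0.214 to 31.5 ± 4.78 CPM (log2 change 5.96 ± 0.176, edgeR adjusted p = 6.56e-17). Glrb rose 38.1-fold from 0.819 ± 0.191 to 31.3 ± 0.832 CPM, Ccl9 31.5-fold and Postn 28-fold to 14.9 ± 1.04 CPM. Krt78 fell 10.7-fold to 8.86 ± 0.552 CPM (log2 change -3.41 ± 0.191, adjusted p = 3.85e-12), Arg1 7.99-fold from 43.8 ± 3.78 CPM, Calca 7.13-fold to 13.4 CPM, and Nr4a1 and the chemokine gene Cxcl17 changed by -2.55 and -2.52 on the log2 scale. Of 43 S phase genes, 36 were higher and 1 lower (37 and 1 adjusted over the list alone, camera adjusted p = 1.26e-12, adjusted p = 0.187 with an estimated correlation), with Ccne1 up 2.65-fold, the licensing factor gene Cdc6 2.36-fold and Pcna, the replication clamp gene, 1.71-fold. Recombination repair genes were higher for 18 of 18 (the same adjusted over the list alone, camera adjusted p = 7.54e-09, adjusted p = 0.095 with an estimated correlation), Brca1 by 2.17-fold. Of 54 G2 and mitosis genes, 27 were higher and 2 lower (32 and 2 adjusted over the list alone, camera adjusted p = 3.43e-07, adjusted p = 0.406 with an estimated correlation), Mybl2 by 1.94-fold.

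Interferon-stimulated genes were higher with PF-06873600 for 27 of 37 with 0 lower (29 and 0 adjusted over the list alone, camera adjusted p = 2.77e-08, adjusted p = 0.234 with an estimated correlation), Usp18 by 11.6-fold and Ifit3, which has a near-identical copy, by 5.72-fold. NF-kB targets were higher for 11 of 17 and lower for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.08e-05), with Tnfaip2 up 9.25-fold and Relb 3.13-fold. Secretory cytokine genes were higher for 8 of 14 (9 adjusted over the list alone, camera adjusted p = 5.63e-05). Of 25 matrix and growth factor genes, 14 were higher and 3 lower (15 and 3 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.0684 with an estimated correlation). Vim (ENSMUSG00000026728.9, chromosome 2, 13573927 to 13582826) rose 4.21-fold from 149 ± 8.29 to 627 ± 16 CPM (edgeR adjusted p = 1.69e-16). Of 14 mesenchymal genes, 8 were higher (10 adjusted over the list alone, camera adjusted p = 3.46e-07). Fibroblast markers were higher for 1 of 4 tested (3 and 0 adjusted over the list alone, camera adjusted p = 0.179). The 3 endothelial and 3 MHC class II genes tested were higher. Cholesterol genes were higher for 16 of 24 (18 adjusted over the list alone, camera adjusted p = 3.43e-07, adjusted p = 0.0684 with an estimated correlation), Hmgcs1 by 1.86-fold. Of 31 lysosomal genes, 17 were higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.39 with an estimated correlation). Tubulin genes were higher for 12 of 16 and lower for 1 (13 and 2 adjusted over the list alone, camera adjusted p = 5.63e-05, adjusted p = 0.192 with an estimated correlation). Of 15 immune ligand genes, 9 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.00405).

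Luminal markers were lower with PF-06873600 for 5 of 8 and higher for 1 (1 and 6 adjusted over the list alone, camera adjusted p = 5.93e-05, adjusted p = 0.0684 with an estimated correlation). Of 14 MAPK output genes, 7 were lower and 1 higher (1 and 7 adjusted over the list alone, camera adjusted p = 0.00475, adjusted p = 0.187 with an estimated correlation). Cdkn1a rose 1.48-fold to 41.2 ± 4.07 CPM (log2 change 0.56 ± 0.0763, edgeR adjusted p = 3.94e-06) and the target gene Cdk6 1.37-fold (adjusted p = 0.00062), while Cdk2 and Cdk4 had log2 changes of -0.06 (0.661) and -0.09 (0.495). The log2 change of Mki67 was 0.51 (adjusted p = 0.0332), with 0.0834 in DESeq2, 0.138 without DMSO 1, 0.126 without DMSO 3 and 0.0743, 0.134 and 0.055 without PF-06873600 1, 2 and 3. Cd274 had 0.74 (adjusted p = 0.0296), with 0.0524 and 0.201 without DMSO 2 and 3 and 0.0649, 0.0809 and 0.0695 without PF-06873600 1, 2 and 3, 0.0667 with no filter, 0.068 without the libraries numbered 2 and 0.0558 with only the 2 groups. Bcl2l1 had 0.18 (adjusted p = 0.0557, with 0.000407 with total counts, 9.3e-05 with limma on TPM, 0.0145 under the block and 0.0454 with only the 2 groups), Cdkn2a 0.02 (0.932), Lmnb1 -0.15 (0.325), Mdm2 0.07 (0.455) and B2m -0.13 (0.335). In all, 4963 genes were called, 2780 higher and 2183 lower, 1238 of them changed at least 2-fold. Higher calls made up 56.0%, and 72.0% with total counts as the scaling.

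Palbociclib, the inhibitor of CDK4 and CDK6, raised Glrb 31.2-fold to 25.7 ± 2.31 CPM (log2 change 4.96 ± 0.178, edgeR adjusted p = 3.12e-15). Il1rl1 rose 18.1-fold, Fgb, the fibrinogen beta chain gene, 10.9-fold from 7.48 ± 2.1 to 81.4 ± 7.16 CPM, and Postn 9.72-fold. Krt78 fell 12.8-fold, Atf3, a stress-induced transcription factor gene, 9.57-fold from 500 ± 64.9 to 52.2 ± 9.95 CPM (adjusted p = 7.4e-13), and Bnip3, a mitophagy gene that low oxygen induces, 9.43-fold from 268 ± 46.1 to 28.4 ± 0.132 CPM. Nr4a1 and Fosb changed by -3.02 and -2.82. G2 and mitosis genes were lower for 27 of 54 with 0 higher (1 higher and 33 lower adjusted over the list alone, camera adjusted p = 6.4e-09, adjusted p = 0.537 with an estimated correlation). Hmgb2, a chromatin protein gene, fell 1.93-fold from 188 to 97.4 CPM and Lmnb1, whose loss is a mark of senescence, 1.82-fold from 65.1 ± 4.58 to 35.9 ± 4.22 CPM (adjusted p = 2.82e-06). Mki67 had a log2 change of -0.13 (adjusted p = 0.605). S phase genes were lower for 18 of 43 and higher for 3 (3 and 19 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.686 with an estimated correlation). Of 18 recombination repair genes, 5 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.325).

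MAPK output genes were lower with palbociclib for 11 of 14 and higher for 1 (1 and 11 adjusted over the list alone, camera adjusted p = 2e-07). Etv4, a transcription factor gene downstream of ERK, fell 4.36-fold from 41.4 ± 3.45 to 9.48 ± 1.22 CPM, and Fosl1 and Etv5 changed by -1.69 and -1.57. Luminal markers were lower for 6 of 8 (6 adjusted over the list alone, camera adjusted p = 3.98e-05, adjusted p = 0.103 with an estimated correlation), with the tight junction gene Cldn4 down 5.19-fold and Krt8 2.66-fold. Of 37 interferon-stimulated genes, 21 were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 4.66e-05, adjusted p = 0.537 with an estimated correlation), Ifit3 by 3.32-fold. Mesenchymal genes were higher for 8 of 14 (8 and 1 adjusted over the list alone, camera adjusted p = 0.000268), Vim by 2.14-fold to 318 ± 12.2 CPM. Cholesterol genes were higher for 15 of 24 (15 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.304 with an estimated correlation). Of 31 lysosomal genes, 14 were higher and 4 lower (14 and 4 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.537 with an estimated correlation). Of 12 protein-coding genes of the mitochondrial genome 8 were higher (9 adjusted over the list alone, camera adjusted p = 0.000716, adjusted p = 0.537 with an estimated correlation), the respiratory complex gene mt-Nd5 by 2.58-fold. Ribosome biogenesis genes were lower for 19 of 47 and higher for 2 (3 and 20 adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.485 with an estimated correlation). Endothelial markers were higher for 1 of 3 and MHC class II genes for 2 of 3.

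Mdm2 (ENSMUSG00000020184.15, chromosome 10, 117688875 to 117710758) rose 1.43-fold with palbociclib, from 79.4 ± 0.678 to 113 ± 1.55 CPM (edgeR adjusted p = 3.23e-06), and B2m, the light chain of MHC class I, 1.39-fold from 1890 ± 214 to 2640 ± 164 CPM (adjusted p = 0.000661). Among the targets Cdk6 rose 1.43-fold (adjusted p = 0.000187) and Cdk4 fell 1.27-fold (adjusted p = 0.00433). The log2 change of Cdkn1a was 0.21 (adjusted p = 0.0361), and leaving out any 1 of DMSO 1, 2 and 3 and Palbociclib 1, 2 and 3 gave 0.151, 0.0753, 0.131, 0.116, 0.0561 and 0.148, no filter 0.271 and leaving out the libraries numbered 2 0.0596. Cd274 had 0.9 (adjusted p = 0.00779, and 0.0649 without DMSO 3), Bcl2l1 -0.23 (0.0137, with 0.0931 without Palbociclib 3 and 0.102 with limma on TPM), Cdk2 -0.32 (0.0125, with 0.128 with total counts, 0.303 with limma on TPM, 0.064 without the libraries numbered 2 and 0.0539 without Palbociclib 2) and Cdkn2a -0.15 (0.342). In all, 5574 genes were called, 2869 higher and 2705 lower, and 1261 changed at least 2-fold. Higher calls made up 51.5%, and 65.6% with total counts as the scaling.

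T/P, trametinib with palbociclib, raised Glrb 35.7-fold to 29.4 ± 3.48 CPM (log2 change 5.16 ± 0.176), Il1rl1 19.4-fold, Postn 15.3-fold and Fgb 13.6-fold. Krt78 fell 19.7-fold to 4.78 CPM (log2 change -4.3 ± 0.203, edgeR adjusted p = 2.38e-13), Bnip3 9.21-fold and Pdk1, a kinase gene that holds pyruvate from mitochondria, 5.62-fold from 106 to 18.9 CPM, and Arg1 changed by -2.86. MAPK output genes were lower for 11 of 14, higher for 1 (1 and 12 adjusted over the list alone, camera adjusted p = 2.12e-06). Palbociclib alone lowered 11 too (median -0.84, here -0.60). Etv4 fell 5.42-fold to 7.6 ± 1.94 CPM, Etv5 4.21-fold and the ERK phosphatase gene Dusp6 1.91-fold from 77.1 ± 13.7 to 40.4 CPM. Trametinib's target gene Map2k1 fell 1.56-fold (adjusted p = 2.18e-06), while Map2k2 changed by -0.02 (0.867). Cholesterol genes were higher for 19 of 24 (19 adjusted over the list alone, camera adjusted p = 4.29e-10), Msmo1 by 1.91-fold. Lysosomal genes were higher for 21 of 31 and lower for 1 (23 and 2 adjusted over the list alone, camera adjusted p = 4.24e-09, adjusted p = 0.197 with an estimated correlation), with the sialidase gene Neu1 up 2.1-fold and the membrane protein gene Lamp1 1.73-fold from 813 to 1400 CPM.

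Of 54 G2 and mitosis genes, 19 were lower with T/P and 0 higher (0 and 24 adjusted over the list alone, camera adjusted p = 1.91e-06, adjusted p = 0.525 with an estimated correlation), and Lmnb1 fell 1.8-fold (edgeR adjusted p = 3.28e-06). Of 43 S phase genes, 2 were higher and 11 lower (camera adjusted p = 0.142, and 0.0358 without T/P 2). Mesenchymal genes were higher for 8 of 14 (8 adjusted over the list alone, camera adjusted p = 1.91e-06), Vim by 3.03-fold to 450 CPM. Endothelial markers were higher for 1 of 3 (mean log2 change 2.22), MHC class II genes for 2 of 3 (mean 2.01) and fibroblast markers for 0 of 4. Of 37 interferon-stimulated genes, 21 were higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 0.000173, adjusted p = 0.525 with an estimated correlation), Ifit3 by 3.51-fold. Of 17 NF-kB targets, 8 were higher and 1 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.197 with an estimated correlation). Luminal markers were lower for 6 of 8 (6 adjusted over the list alone, camera adjusted p = 0.000202, adjusted p = 0.156 with an estimated correlation), Cldn4 by 6.76-fold. Of 12 mitochondrial genes, 6 were higher (7 adjusted over the list alone, camera adjusted p = 0.00279, adjusted p = 0.525 with an estimated correlation). Cdkn1a rose 1.51-fold to 42.2 ± 2.63 CPM (log2 change 0.6 ± 0.0763, adjusted p = 1.77e-06), Mdm2 1.44-fold (2.58e-06), B2m 1.43-fold (0.000328) and Cdk6 by 0.45 (0.000782), and Cdk2 fell 1.36-fold (0.00103). Mki67 had a log2 change of -0.09 (adjusted p = 0.766), Cd274 0.43 (0.232), Cdkn2a 0.1 (0.559), Bcl2l1 -0.06 (0.561) and Cdk4 -0.19 (0.121, with 0.037 without DMSO 3, 0.0268 without T/P 2 and 0.0278 under the block). In all, 4605 genes were called, 2340 higher and 2265 lower, and 932 changed at least 2-fold.

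Nutlin, which keeps MDM2 from binding p53, lowered cell cycle genes. All 54 G2 and mitosis genes were lower (54 adjusted over the list alone, camera adjusted p = 4.45e-53). Foxm1, a transcription factor gene of mitotic genes, fell 2.82-fold (log2 change -1.5 ± 0.138, edgeR adjusted p = 5e-08), Mki67 2.5-fold to 27.9 ± 10.4 CPM (adjusted p = 1.63e-05) and Lmnb1 2.32-fold to 28 CPM. S phase genes were lower for 38 of 43 (40 adjusted over the list alone, camera adjusted p = 9.04e-30), the helicase gene Mcm6 by 2.18-fold. Of 18 recombination repair genes, 15 were lower (17 adjusted over the list alone, camera adjusted p = 2.85e-13), Fancd2 by 3.13-fold. MAPK output genes were lower for 10 of 14 (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 7.3e-10), with Etv4 down 8.7-fold to 4.73 CPM (log2 change -3.12 ± 0.146) and Etv5 7.8-fold. Other large falls were in Fbln2, a matrix gene, 13.4-fold from 10 to 0.758 CPM, Krt78 6.52-fold and Arg1 5.89-fold. The largest rises were smaller than in the other groups, with Glrb at 4.31-fold, Ogn, a matrix proteoglycan gene, and the trehalase gene Treh both at 3.68-fold, Chac1, which encodes an enzyme that breaks down glutathione, at 3.61-fold from 13.7 to 49.6 CPM and Fgb at 3.15-fold.

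Lysosomal genes were higher with Nutlin for 18 of 31 and lower for 1 (20 and 2 adjusted over the list alone, camera adjusted p = 1.11e-12, adjusted p = 0.0956 with an estimated correlation), Neu1 by 1.85-fold. Genes of the unfolded protein and integrated stress responses were higher for 15 of 23 and lower for 3 (16 and 5 adjusted over the list alone, camera adjusted p = 4.6e-08, adjusted p = 0.0758 with an estimated correlation), Trib3 by 2.99-fold and Herpud1 by 1.86-fold. MHC class I genes were higher for 10 of 21 with 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 4.09e-05, adjusted p = 0.28 with an estimated correlation), with B2m (ENSMUSG00000060802.8, chromosome 2, 122147686 to 122153083) up 1.65-fold to 3120 ± 87.6 CPM (edgeR adjusted p = 1.07e-05) and the peptide-loading gene Tapbp 1.56-fold. Basal markers were lower for 5 of 9 (6 adjusted over the list alone, camera adjusted p = 0.000207). Of 8 luminal markers, 3 were lower (4 adjusted over the list alone, camera adjusted p = 0.000742, adjusted p = 0.124 with an estimated correlation). Of 16 tubulin genes, 6 were lower and 1 higher (1 and 8 adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.344 with an estimated correlation). Cholesterol genes were higher for 4 of 24 (the same adjusted over the list alone, camera adjusted p = 0.00845, adjusted p = 0.344 with an estimated correlation, and 0.131 without Nutlin 2).

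Mdm2 rose 1.33-fold to 106 ± 3.31 CPM with Nutlin (log2 change 0.41 ± 0.0684, edgeR adjusted p = 0.000106) and Cdkn1a 1.26-fold to 35.2 ± 0.459 CPM (0.33 ± 0.0771, adjusted p = 0.003). Both are direct p53 targets, and of 29 p53 target genes 6 were higher and 3 lower (6 and 3 adjusted over the list alone), with camera adjusted p = 0.168. Bcl2l1 changed by -0.35 (edgeR adjusted p = 0.000984), and Cdkn2a and Cd274 had log2 changes of -0.18 (0.334) and 0.37 (0.365). In all, 3011 genes were called, 1245 higher and 1766 lower, and 577 changed at least 2-fold. The count was 2002 without Nutlin 1, and 1699 in a fit of only the Nutlin and DMSO libraries.

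**Figure D3:**
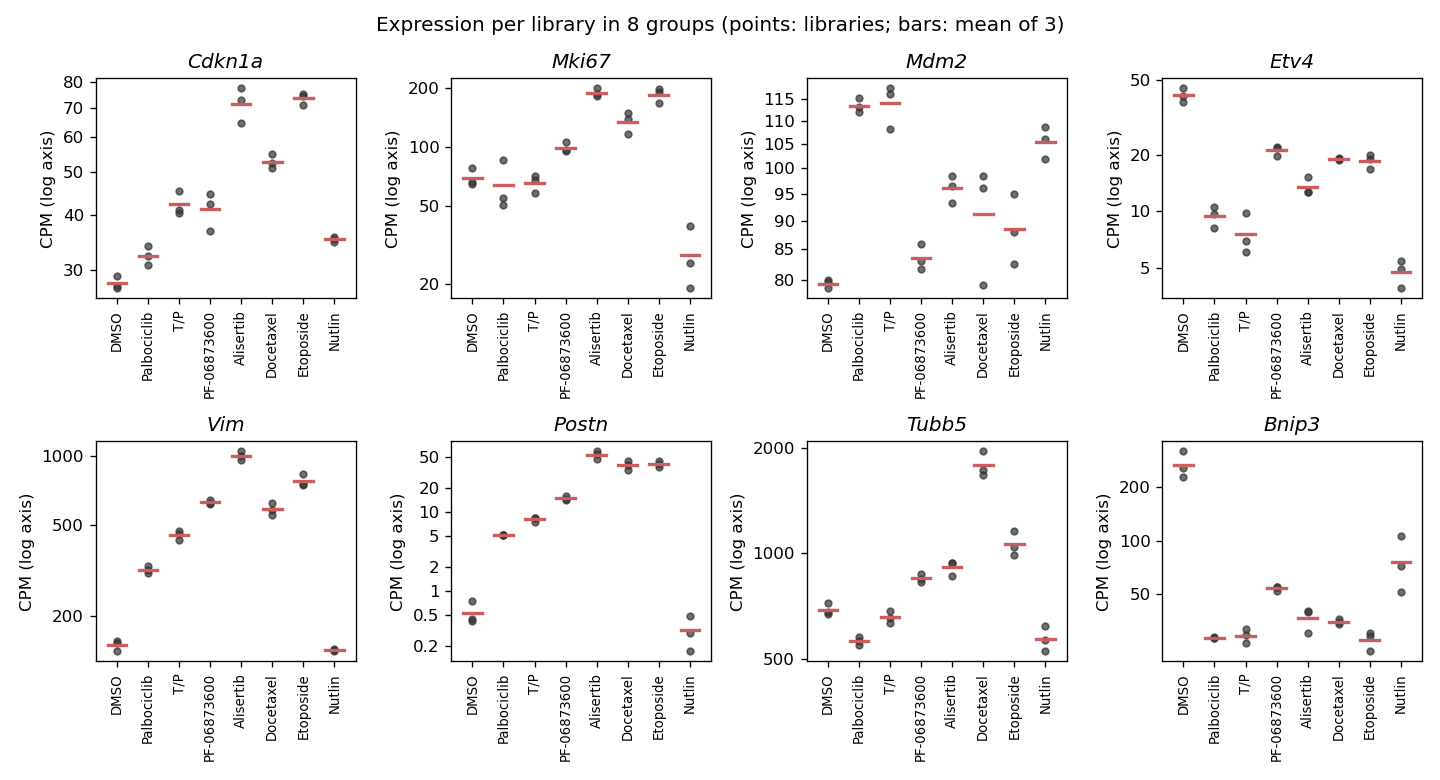
CPM on a log axis of 8 genes in each of 24 libraries (points) with the mean of the 3 libraries of a group (bar). Mki67 was 69.8 CPM in DMSO, 189 with alisertib and 27.9 with Nutlin, and Bnip3 was 268 CPM in DMSO and between 27.6 and 76.4 in the treated groups.

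Across treatments, p53 target genes were not called as a list by camera in any comparison with DMSO (lowest adjusted p = 0.114), although single members rose. The rotation test fry, which does not compare with other genes, called p53 targets higher in 6 of 7, with adjusted p from 1.36e-05 (alisertib) to 0.00488 (Nutlin), and 0.0873 with palbociclib. CDK inhibitor genes (lowest camera adjusted p = 0.154), nucleic acid sensing genes (0.106), anti-apoptotic (0.41) and pro-apoptotic genes (0.425) and NRF2 targets (0.216) were not called with any treatment either. Fry called nucleic acid sensing genes higher with PF-06873600 (0.00755), palbociclib (1.2e-05), T/P (0.000423), alisertib (0.0134) and etoposide (0.000441), and NRF2 targets higher with PF-06873600 (0.0012), T/P (0.0019), alisertib (0.00605) and etoposide (0.00217) and lower with docetaxel (0.0312). It called anti-apoptotic genes higher with palbociclib (0.0408) and lower with etoposide (0.0128), and CDK inhibitor genes lower with palbociclib (0.0065). Markers of immune cells, with 4 tested members, had camera adjusted p = 0.0715 with docetaxel, 0.0728 with etoposide and 0.109 with alisertib, and without DMSO 1 these were 0.0255, 0.0287 and 0.0465. They were also under the threshold for docetaxel without DMSO 3 (0.0382), Docetaxel 2 (0.0342) or Docetaxel 3 (0.0204), and for etoposide without DMSO 3 (0.0493) or Etoposide 1 (0.0417). Basal markers, called with etoposide, were also called higher with alisertib, for 6 of 9 with 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0321, adjusted p = 0.173 with an estimated correlation, 0.0573 with the filter at 1 CPM and 0.0858 without the libraries numbered 2). With PF-06873600 5 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0484, adjusted p = 0.195 with an estimated correlation, 0.0582 under the block, 0.138 without the libraries numbered 2 and 0.0719 without DMSO 2). Mitochondrial genes, called with palbociclib and T/P, were called higher with alisertib too, for 6 of 12 (the same adjusted over the list alone, camera adjusted p = 0.0491, adjusted p = 0.617 with an estimated correlation). The p was 0.0567 with RLE factors, 0.0504 with the filter at 1 CPM, 0.138 without the libraries numbered 2 and 0.168, 0.0884, 0.114 and 0.113 without DMSO 2, DMSO 3, Alisertib 1 and Alisertib 2. With etoposide 6 were higher (the same adjusted over the list alone, camera adjusted p = 0.0423, adjusted p = 0.624 with an estimated correlation), with 0.0502, 0.051 and 0.252 in the same 3 alternatives and 0.105, 0.062, 0.0547 and 0.152 without DMSO 2, DMSO 3, Etoposide 1 and Etoposide 2. With Nutlin 4 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0287, adjusted p = 0.635 with an estimated correlation), with 0.0597 under the block and 0.204, 0.0722 and 0.343 without DMSO 2, DMSO 3 and Nutlin 1. Neuroendocrine markers had 3 tested members and no list test, and 3 were higher with palbociclib, alisertib, docetaxel and etoposide.

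In all 7 treatments 229 genes were higher and 336 lower than in DMSO, 565 in all, of which 70 changed at least 2-fold in each. Higher genes were 40.5% of these, and 56.7% of 612 with total counts as the scaling and 50.9% with limma on TPM. Among those higher everywhere were Glrb, with log2 changes from 2.11 to 5.75, the stress-induced gene Nupr1 (1.41 to 3.44), the prostaglandin D2 synthase gene Ptgds (1.19 to 2.87) and Ddit3, a transcription factor gene of the stress response (1.04 to 1.89). Krt78 (-2.7 to -4.83), Arg1 (-2.5 to -3.96), Bnip3 (-1.81 to -3.28), Krt4 (-1.77 to -3.49) and the collagen-modifying enzyme gene Plod2 (-1.58 to -2.37) were lower everywhere. The shared genes included the lysosomal genes Lamp1, Lamp2, Ctsl and Man2b1 and the p53 targets Cdkn1a, Sesn2 and Zmat3 among those higher, and the MAPK output genes Spred1, Etv4, Etv5 and Ier3 and the luminal keratin genes Krt8 and Krt19 among those lower. The call of Cdkn1a with palbociclib did not hold without any 1 of its 6 libraries, with adjusted p between 0.0561 and 0.151. Independent lists of these sizes would share 0.127 genes higher and 0.0997 lower. A mean of 0 in 5 simulations sharing the 3 DMSO libraries is no chance level, as no gene changed there. The 7 comparisons share controls, too few to split, so an unusual DMSO level enters all.

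The profiles of alisertib and etoposide were close. Across genes, which are not independent replicates, their log2 changes from DMSO had r = 0.949 and a covariance of 1.72, against 0.114 in simulated unchanged groups with shared controls. Over 21 pairs of treatments the median r was 0.745, against 0.514 in those simulations. Palbociclib and T/P had r = 0.813. Etoposide and Nutlin had r = 0.0987 with a covariance of 0.0920, against 0.115 simulated, and 1170 genes were called in opposite directions.

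T/P was compared with palbociclib to ask what trametinib adds. Atf3 was 4.9-fold higher with T/P, 256 ± 3 against 52.2 ± 9.95 CPM (log2 difference 2.29 ± 0.158, edgeR adjusted p = 2.62e-09). Id3, an inhibitor of differentiation factors, was 3.85-fold higher at 154 ± 26.8 against 40.1 CPM, and Nr4a1 3.59-fold higher. The zinc finger gene Zfp866 was 2.77-fold and Ccnb1ip1, a ligase gene of meiotic recombination, 2.35-fold lower with T/P (adjusted p = 1.6e-05 and 0.000348). Of 23 stress response genes 8 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 5.54e-07, adjusted p = 0.17 with an estimated correlation), Chac1 by 1.78-fold. Cholesterol genes were higher for 4 of 24 (7 and 1 adjusted over the list alone, camera adjusted p = 1.58e-06, adjusted p = 0.17 with an estimated correlation). Of 31 lysosomal genes, 2 were higher (5 adjusted over the list alone, camera adjusted p = 8.66e-07, adjusted p = 0.302 with an estimated correlation). Of 47 ribosome biogenesis genes, 3 were higher (3 adjusted over the list alone, camera adjusted p = 2.78e-05, adjusted p = 0.217 with an estimated correlation). Tubulin genes were higher for 2 of 16 (7 adjusted over the list alone, camera adjusted p = 0.000171, adjusted p = 0.302 with an estimated correlation). Of 14 mesenchymal genes, 2 were higher (the same adjusted over the list alone, camera adjusted p = 0.00514, adjusted p = 0.17 with an estimated correlation). Of 15 NRF2 targets, 2 were higher (3 adjusted over the list alone, camera adjusted p = 0.00526, adjusted p = 0.2 with an estimated correlation). MAPK output genes were higher for 4 of 14 and lower for 1 (4 and 2 adjusted over the list alone, camera adjusted p = 0.129, and 0.0183 without T/P 2).

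Cdkn1a was 1.31-fold higher with T/P than with palbociclib, 42.2 against 32.3 CPM (edgeR adjusted p = 0.00499). Mki67 had a log2 difference of 0.04 (adjusted p = 0.916, 95% interval -0.33 to 0.42) and B2m one of 0.04 (0.861). Of 43 S phase genes 1 was higher (the same adjusted over the list alone, camera adjusted p = 0.00447, adjusted p = 0.654 with an estimated correlation, 0.179 without Palbociclib 1 and 0.0667 without the libraries numbered 2). Camera called G2 and mitosis genes higher with a median of 0.10, while 0 of 54 were called higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.793 with an estimated correlation), with 0.184, 0.523 and 0.133 without T/P 2, Palbociclib 1 and Palbociclib 2, 0.255 without the libraries numbered 2 and 0.0512 with the filter at 1 CPM. Of 29 p53 targets 3 were higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.2 with an estimated correlation, 0.132 without T/P 3 and 0.0606 with the filter at 1 CPM). In all, 637 genes were called, 254 higher and 383 lower, and 106 differed at least 2-fold. The count was 154 without T/P 2, 230, 249 and 238 without Palbociclib 1, 2 and 3, and 411 without the libraries numbered 2, and DESeq2 gave 51.9% higher against 39.9%. Of 17 nuclear-retained transcripts 1 was lower with T/P, and 13 without the libraries numbered 2.

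PF-06873600 was compared with palbociclib to set an inhibitor that also blocks CDK2 beside one of CDK4 and CDK6, though at different doses, 500 nM and 1 µM. C3 was 6.1-fold higher with PF-06873600, 33.9 against 5.56 CPM (log2 difference 2.61 ± 0.158, edgeR adjusted p = 1.55e-10), the chemokine gene Cxcl5 3.76-fold at 27.4 against 7.28 CPM and Il1rl1 3.46-fold, and Fgb was 4.46-fold lower (-2.16 ± 0.172, adjusted p = 9.51e-09). G2 and mitosis genes were higher for 51 of 54 and lower for 1 (51 and 1 adjusted over the list alone, camera adjusted p = 1.24e-30, adjusted p = 0.102 with an estimated correlation), with Mybl2 up 2.13-fold and Hmgb2 2.03-fold at 198 against 97.4 CPM. S phase genes were higher for 40 of 43 (40 adjusted over the list alone, camera adjusted p = 5.47e-29), Pcna by 2.17-fold. Of 18 recombination repair genes, 12 were higher (15 adjusted over the list alone, camera adjusted p = 2.41e-08, adjusted p = 0.102 with an estimated correlation). MAPK output genes were higher for 10 of 14 (11 and 1 adjusted over the list alone, camera adjusted p = 1.3e-05). Of 17 NF-kB targets, 9 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.000199). Of 14 secretory cytokine genes, 4 were higher (the same adjusted over the list alone, camera adjusted p = 0.000554). Of 14 mesenchymal genes, 5 were higher (6 adjusted over the list alone, camera adjusted p = 0.00171). Tubulin genes were higher for 10 of 16 (12 adjusted over the list alone, camera adjusted p = 7.93e-07, adjusted p = 0.102 with an estimated correlation). Of 47 ribosome biogenesis genes, 13 were higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.000276, adjusted p = 0.206 with an estimated correlation).

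B2m was 1.53-fold lower with PF-06873600 than with palbociclib, 1730 against 2640 CPM (edgeR adjusted p = 0.00011). Cdkn1a had a log2 difference of 0.35 (adjusted p = 0.00157, and 0.0832 without the libraries numbered 2) and Mki67 one of 0.64 (0.0114, with 0.0804 and 0.0643 without Palbociclib 1 and 2 and 0.0541 without the libraries numbered 2). In all, 4057 genes were called, 2241 higher and 1816 lower, and 685 differed at least 2-fold. Mitochondrial genes were lower for 2 of 12 (the same adjusted over the list alone, camera adjusted p = 0.00945, adjusted p = 0.442 with an estimated correlation). Nuclear-retained transcripts were lower with PF-06873600 for 11 of 17, and for 16 without the libraries numbered 2.

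Docetaxel was compared with alisertib, since both act on mitosis, through microtubules and through Aurora A. Cholesterol genes were higher with docetaxel for 21 of 24 (21 adjusted over the list alone, camera adjusted p = 5.3e-20). Egr1, an early-response transcription factor gene, was 4.85-fold higher at 323 against 66.5 CPM (log2 difference 2.28 ± 0.179, edgeR adjusted p = 7.07e-09), the linker histone gene H1f0 3.26-fold and Ier2 2.99-fold. Glrb was 3.66-fold lower with docetaxel (-1.87 ± 0.12, adjusted p = 6.78e-10) and the peptide transporter gene Slc15a3 3.52-fold. Of 54 G2 and mitosis genes, 31 were lower (42 adjusted over the list alone, camera adjusted p = 9.16e-19, adjusted p = 0.203 with an estimated correlation). Of 43 S phase genes, 19 were lower (22 adjusted over the list alone, camera adjusted p = 1.28e-12, adjusted p = 0.203 with an estimated correlation). Of 18 recombination repair genes, 13 were lower (17 adjusted over the list alone, camera adjusted p = 2.72e-13, adjusted p = 0.0621 with an estimated correlation). Stress response genes were lower for 11 of 23 and higher for 1 (the same adjusted over the list alone, camera adjusted p = 4.91e-06, adjusted p = 0.196 with an estimated correlation). Of 14 mesenchymal genes, 8 were lower (2 and 8 adjusted over the list alone, camera adjusted p = 3.61e-05). MAPK output genes were higher for 7 of 14 (9 adjusted over the list alone, camera adjusted p = 2.19e-05, adjusted p = 0.0621 with an estimated correlation). Of 16 tubulin genes, 10 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.000117, adjusted p = 0.203 with an estimated correlation). Of 8 luminal markers, 4 were higher (5 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.203 with an estimated correlation).

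Cdkn1a was 1.36-fold lower with docetaxel than with alisertib (log2 difference -0.44 ± 0.073, edgeR adjusted p = 0.000204), and Mki67 and B2m had log2 differences of -0.5 (0.0541, and 1.14e-07 to 0.0468 in 5 alternatives) and -0.1 (0.531). In all, 2707 genes were called, 1339 higher and 1368 lower, and 396 differed at least 2-fold. The count was 1804 without Alisertib 3.

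Etoposide was compared with docetaxel, a drug of DNA breaks with a drug of the spindle. S phase genes were higher with etoposide for 40 of 43 (41 adjusted over the list alone, camera adjusted p = 5.56e-28, adjusted p = 0.0839 with an estimated correlation), Ccne1 by 2.17-fold, and all 18 recombination repair genes were higher (the same adjusted over the list alone, camera adjusted p = 1.81e-14, adjusted p = 0.0839 with an estimated correlation), Fancb by 2.2-fold and Bard1 by 2.06-fold. G2 and mitosis genes were higher for 41 of 54 and lower for 1 (45 and 1 adjusted over the list alone, camera adjusted p = 2.55e-16, adjusted p = 0.275 with an estimated correlation). Interferon-stimulated genes were higher for 31 of 37 with 0 lower (31 and 0 adjusted over the list alone, camera adjusted p = 2.25e-13, adjusted p = 0.21 with an estimated correlation), Ifit3 by 3.34-fold at 12.5 ± 4.54 against 3.7 CPM and Ifi27 by 2.46-fold. Cholesterol genes were lower for 20 of 24 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 6.06e-12, adjusted p = 0.0564 with an estimated correlation). Il1rl1 was 4.14-fold higher with etoposide (log2 difference 2.05 ± 0.114, edgeR adjusted p = 1e-11). Calca was 4.53-fold, Krt19 4.26-fold and the glycolytic aldolase gene Aldoc 3.49-fold lower.

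Stress response genes were higher with etoposide than with docetaxel for 12 of 23 and lower for 2 (13 and 3 adjusted over the list alone, camera adjusted p = 8.35e-05, adjusted p = 0.216 with an estimated correlation). Of 14 mesenchymal genes, 6 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.134 with an estimated correlation). Cdkn1a was 1.39-fold higher (edgeR adjusted p = 2.49e-05), and B2m had a log2 difference of -0.11 (0.457). In all, 4726 genes were called, 2207 higher and 2519 lower, and 845 differed at least 2-fold.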

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

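Leaving out the libraries numbered 2 and limma on TPM were chosen after seeing the data, other alternatives before. The direction reversed for Bcl2l1 with alisertib, at 0.16 with total counts and 0.22 with limma on TPM, against -0.03 in edgeR with TMM. With limma on TPM it also reversed for Cdkn2a with docetaxel (0.22) and Bcl2l1 with docetaxel (0.13). Over genes with a mean of at least 10 CPM the similarity to Nutlin became -0.0326 for alisertib and -0.111 for etoposide, and the median over pairs was 0.705. The cause was not tested. None of these changes from DMSO was called in edgeR with TMM.

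Changes of at least 2-fold are a stricter requirement by construction. In the order of the next paragraph they numbered 1238, 1261, 932, 2848, 2616, 3010 and 577 against DMSO. Between treatments they numbered 106, 685, 396 and 845, and 70 were shared by all 7 treatments. Apart from that requirement the count for T/P against palbociclib moved, from 637 to 1148 with DESeq2, 1181 with no filter, 2504 with the block for library number, 1165 with only the 2 groups, 411 without the libraries numbered 2 and 317 with limma on TPM. For Nutlin against DMSO only the 2 groups gave 1699. The cause was not tested.

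With an estimated correlation between genes camera called 4, 2, 3, 5, 5, 4 and 5 lists for PF-06873600, palbociclib, T/P, alisertib, docetaxel, etoposide and Nutlin against DMSO, and 0, 6, 2 and 0 for T/P against palbociclib, PF-06873600 against palbociclib, docetaxel against alisertib and etoposide against docetaxel. The preset correlation gave 16, 10, 9, 16, 14, 15 and 12 and then 10, 14, 11 and 11. For the pairs with 0, fry called 9 and 19 lists. It called 19 lists for palbociclib, 18 for T/P and 24 for etoposide against DMSO, and asks another question by construction.

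Leaving out 1 library at a time gave 4164 to 4485, 4402 to 5217 and 3898 to 4095 genes against DMSO, in the order above. It then gave 7577 to 8046, 6663 to 7464, 7895 to 8209 and 2002 (without Nutlin 1) to 3459. Between treatments it gave 154 (without T/P 2) to 480, 2730 to 3236, 1804 (without Alisertib 3) to 2444 and 3569 to 4305. T/P against palbociclib also fell to 230, 249 and 238 without Palbociclib 1, 2 and 3. The genes shared by all 7 treatments numbered 388 to 630. Lists called were 14 to 17 for PF-06873600, 10 for palbociclib, 9 to 10 for T/P, 15 to 18 for alisertib, 14 to 16 for docetaxel, 14 to 16 for etoposide, 11 to 12 for Nutlin, and 8 to 11, 12 to 14, 11 to 12 and 8 to 13 for the comparisons between treatments in the order above.

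Of the values for named genes, 350 of 359 kept their side of the threshold, and their direction where called, with total counts, 356 with RLE factors, 353 of 358 with DESeq2, 353 of 359 with no filter, 354 with the block, 345 without the libraries numbered 2, 344 with limma on TPM and 2083 of 2154 with 1 library left out. Of the values for lists, 206 of 308 did so with an estimated correlation, 232 with fry, 301 with the block and 301 with RLE factors. Values not called in either setting changed sign for 12 genes with total counts, 9 with limma on TPM and 25 with 1 library left out, and for 9 lists with fry, 5 with the block and 1 with RLE factors. Depth limits genes near 0 counts in DMSO, such as Ccl2 with 4 counts and Cxcl10 with 3, for which no fold is given.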

Other observations

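The scaling, DMSO culture, depth, fibroblast and shared-batch tests, and the hypoxia gene list, were chosen only after the results were seen. Genes that low oxygen induces were lower in every treatment than in DMSO. On the log2 scale the glucose transporter gene Slc2a1 changed by -1.65 with PF-06873600, -1.87 with palbociclib, -2.10 with docetaxel and -0.96 with Nutlin, and the glycolytic genes Pgk1 and Ldha by -1.10 and -1.13 with Nutlin (edgeR adjusted p = 5.68e-06 and 4.2e-07). Of 25 list members not seen before the list was written, 21 or 22 were lower in each of the 7 treatments, with a median from -0.83 (Nutlin) to -1.24 (docetaxel). With an estimated correlation camera gave adjusted p = 0.0217 for PF-06873600, 0.0181 for palbociclib, 0.0296 for T/P, 0.0342 for docetaxel, 0.0287 for Nutlin, 0.0626 for alisertib and 0.0916 for etoposide.

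G2 and mitosis genes were above DMSO with PF-06873600, alisertib, docetaxel and etoposide, with medians of 0.42, 1.17, 0.70 and 1.24. The scaling between libraries is argued against, since other scalings left at least 0.960 of the median, and so is unequal nuclear RNA, since a covariate for it left at least 0.867. Crowded, oxygen-poor DMSO cultures with few dividing cells may explain the pattern, because the unseen hypoxia genes had a median of -0.849 or lower in these 4 treatments. That cannot be told apart from a drug effect, since the state of the DMSO cultures is confounded with the comparison. Palbociclib and T/P, with hypoxia medians of -1.15 and -1.04, had G2 and mitosis medians of -0.40 and -0.31, and Nutlin, with -0.83, had -1.42, so a fall of hypoxia genes did not go with higher G2 and mitosis genes in these 3.

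More genes were detected with alisertib, docetaxel and etoposide than in DMSO. Depth is argued against, since thinned to equal counts the lowest treated library had 21282 genes, 2465 above the highest DMSO library (18817). Genomic DNA is argued against as the whole cause, since receptor genes gained reads at no more than 0.245 of the share of other genes of like length. A part is left open, since 8.05, 13.3 and 8.12% of receptor genes gained reads, in that order, against 2.40% with Nutlin (ratio 0.205). Fibroblasts rich in Col1a2, Col3a1 and Lum are argued against as the whole cause, since these genes, at 0 counts in DMSO, stayed at 0.0755 CPM or less, Lum at 0. With alisertib, docetaxel and etoposide 286, 545 and 514 other protein-coding genes at 0 counts in DMSO had more counts than the upper 95% Poisson limit of these 3. Dcn, at 0.487 to 1.20 CPM, was among the genes gained. Col1a1 had 0.665 to 1.15, Pdgfra 20.6 to 26 and Sparc 302 to 460 CPM. Other fibroblasts, other cell types and a drug effect on silent genes were not tested.

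Nuclear-retained transcripts were low in the libraries numbered 2 of 7 groups, for example Neat1 at 298 CPM in Alisertib 2 against 931 and 725. GC content and transcript length are argued against, since 0.896 of the median deviation stayed after their trend was removed. The deviations of these 7 libraries correlated at 0.271 or more with each other, but the libraries were singled out by that deviation, so the value decides nothing about a shared day or library batch. Such a batch cannot be told apart from other causes, because the labels give 1 batch, and no biological explanation was tested.

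The 10 splits of 3 libraries against 3 are too few for a share under 0.05, and only the real one gave as many genes. In fits of the 6 libraries the real splits gave 4593 genes for PF-06873600, 5870 for palbociclib, 3654 for T/P, 7008 for alisertib, 6799 for docetaxel, 7262 for etoposide and 1699 for Nutlin against DMSO. Between treatments they gave 1165, 5835, 2211 and 4175, in the order used above. The highest of the other splits was 0 in edgeR for each, with 382, 216, 765, 324, 649, 290, 1509, 927, 189, 958 and 1108 genes at an unadjusted p under 0.05 in the same order.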
